A study of Mus musculus with 3 samples.

How the data were processed

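Gene expression was measured by RNA sequencing of total RNA, extracted with TRIzol, from the liver of male C57BL/6 mice aged 14 weeks, on an Illumina instrument. There were 3 libraries with 1 per group: regular chow, a high-fat diet, and the high-fat diet with DfCS-Ib, a sulfated oligosaccharide by the series' design text, given by gavage at 40 mg/kg. The labels give 8 mice per group and free access to food, mention more groups than the 3 they describe, and do not state how many mice gave the RNA of each library.

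The authors deposited, for each library, raw read counts for 41799 genes and the RPKM computed from them, per the file headers, with each gene's type, mm10 position, strand and length. The RPKM given by the authors was the count scaled by the stated length and by the file's own total, which held to within 0.000506% for genes with at least 100 counts. Reads were aligned with TopHat2 to mm10, per the submitters' processing notes. The counting tool, its strand setting, its treatment of reads with several placements and the annotation release are not given in the sources used here. Genes with near-identical copies, such as the Saa, Mup, Orm, Cyp4a, Cyp3a, Cyp2c, Hsd3b, Acot, glutathione transferase and globin families, and genes that overlap another gene are therefore uncertain. Of the 41799 genes, 1144 lie off the main chromosomes and 889 of these are listed at 0 in all 3 libraries; of 22052 protein-coding genes, 6377 are listed at 0. Some genes with known liver expression are among them, so a gene listed at 0 is not shown to be unexpressed, and low counts may be understated. For 43 of the 576 distinct genes of the lists this was so. Gapdh, a gene with many pseudogene copies, had 86, 90 and 71 counts in the chow, high-fat and DfCS-Ib libraries.

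Total counts were 11028671 for chow, 12279537 for the high-fat diet and 10969699 for DfCS-Ib, which were used as the depth of each library. A gene listed at 0 could still have up to 3 counts, which is 0.279, 0.233 and 0.280 CPM (counts scaled to a common library size) in the same order, for counting error only. Albumin took 11.0% (10.98 to 11.02), 8.91% (8.90 to 8.93) and 9.19% (9.17 to 9.21) of the counts, and ribosomal RNA genes 0.567% (0.562 to 0.571), 0.546% (0.541 to 0.550) and 0.674% (0.669 to 0.679). The 50 genes with the highest mean count over the 3 libraries took 38.5%, 34.1% and 36.9%. Intervals are 95% exact (Clopper-Pearson) intervals. Reads carried no molecular identifiers that the sources used here name, and the intervals and floors cover counting error only.

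Counts were scaled to CPM with TMM factors of 0.976, 1.048 and 0.978 (edgeR 4.0.16 in R 4.3.3). The log2 ratio of a pair of libraries was taken on CPM plus 1, which understates the difference of genes with few reads. Genes with a mean of at least 1 CPM over the 3 libraries were analysed, 13153 in all. Folds of single genes in the text are ratios of scaled counts with no pseudocount, with an exact interval from the binomial split of the gene's counts in the libraries compared. With 1 library per group no p-value was computed; a gene was counted where the ratio was at least 2-fold, and a library was said to stand apart for a gene where it lay at least 2-fold from both others and these lay within 1.5-fold of each other. The comparisons were the high-fat diet with chow, DfCS-Ib with the high-fat diet and DfCS-Ib with chow.

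For 34 gene lists, 19 of functions and 15 of cell types and liver zones, the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. A median outside the central 95% was said to stand apart, as a description of these libraries. Most medians of the function lists stood apart, so this alone does not mark a list as unusual. They included small ones for DfCS-Ib with chow, such as 0.12 for cholesterol, -0.12 for glucose and -0.16 for respiratory chain genes. The lists, the comparisons, the 2-fold rule, the rule for named genes and most alternatives were fixed before the data were examined; the choice of CPM without TMM factors, DESeq2 size factors, RPKM, thinning and a counting interval as alternatives came afterwards. The function lists covered cholesterol synthesis and uptake, fatty acid and triglyceride synthesis, fatty acid oxidation with PPAR alpha targets, lipid droplets, bile acids, lipoproteins, glucose metabolism, inflammation, acute phase proteins, interferon response, extracellular matrix, antioxidant defence, drug-metabolising cytochromes, circadian clock, unfolded protein response, male-biased and female-biased genes, respiratory chain and cell cycle. The others covered hepatocytes, macrophages and Kupffer cells, monocytes, T and NK cells, B cells, neutrophils, endothelium, stellate cells, cholangiocytes, erythroid cells, exocrine pancreas, adipocytes, skeletal muscle and the pericentral and periportal zones. Of 588 list entries, 586 were matched to a gene, 3 of them by an older symbol. Symbols that had been turned into dates (27 genes) were restored from the NCBI gene numbers in the files and a table of mouse RefSeq genes.

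Unnamed gene models, pseudogenes and small RNAs with names such as Mir, Snor, Scarna and Rnu were left out of the naming, but transfer RNAs such as TrnG were not. Named genes were, for each comparison, the 12 with the largest ratio in each direction among genes with at least 5 CPM in the higher library. To these were added up to 4 members with the largest ratios from each list that stood apart or had at least 3 members 2-fold apart, and a fixed set of lipid and glucose genes whatever their values, among them Cyp7a1, Fasn, Scd1, Srebf1, Ppara, Cpt1a, Cd36, Cidec, Pparg and G6pc, which gave 180 genes. Some of these genes are not reported here.

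The procedure was tested on counts simulated for the high-fat and chow libraries over 13124 genes, with 200 genes changed at each size. Of the genes changed 1.5-fold, 0.5% were counted, of those changed 2.5-fold 84.5% and of those changed 4-fold 98.5%, and 0 of 12524 unchanged genes were counted. Of 100 unchanged lists of 20 genes, 5 stood apart, and of 100 lists raised 1.5-fold, all drawn from the same pool of changed genes, all 100 did. The simulated counts held counting noise only, with genes varying independently and no spread between mice. These rates therefore do not carry over to lists of genes that vary together in the real libraries. Counts drawn from counting noise alone for 13144 genes gave 1, 4 and 3 genes for the comparisons in the order above.

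The counts, the medians of the 29 lists with at least 3 measured members and the named genes were recomputed, where a version measured them, with a pseudocount of 0.1, no filter on low values, a mean of at least 5 CPM, libraries scaled to a median log2 ratio of 0, the 50 most abundant genes left out, protein-coding genes only, thresholds of 1.5-fold and 4-fold for the counts, CPM without TMM factors, DESeq2 1.42.0 size factors, the authors' RPKM, libraries thinned to the smallest total and, for the counts, a counting interval that excludes 1. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.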

Results

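RNA sequencing was carried out on liver from male C57BL/6 mice aged 14 weeks, with 1 library from each of 3 groups: mice on regular chow, mice on a high-fat diet, and mice on the high-fat diet that were also given DfCS-Ib by gavage at 40 mg/kg. DfCS-Ib is a code name, and the series describes the treatment as a sulfated oligosaccharide. The labels give groups of 8 mice but not how many of them contributed RNA to a library. The chow, high-fat and DfCS-Ib libraries held 11028671, 12279537 and 10969699 counts, with at least 1 count in 19916, 20283 and 19943 genes. Mitochondrial genes took 5.38% (5.37 to 5.39), 4.79% (4.78 to 4.81) and 5.24% (5.23 to 5.25) of the counts in the same order. Because each group had 1 library, no difference between groups has a replicate check, and every comparison describes these libraries and not the conditions. Fold values come from the scaled counts, and the ranges in parentheses beside them and beside the shares are 95% exact (Clopper-Pearson) intervals, which cover counting error only. Medians of gene lists are log2 ratios of CPM, the counts scaled to a common library size, plus 1, and each is set against 10000 random lists matched on expression. Most medians of the function lists lay outside the central 95% of the random lists, so a place outside it was not rare here. The numbers of members at least 2-fold higher or lower rest on the same log2 ratios.

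The comparison of the high-fat and chow libraries asked what went with the diet. Genes of cholesterol synthesis and uptake were higher in the high-fat library almost throughout: 21 of the 25 measured members were at least 2-fold higher and 0 at least 2-fold lower. The list's median log2 ratio was 2.31, above all 10000 random lists. Sqle, which encodes squalene epoxidase and lies on chromosome 15, 59315092 to 59331193 of mm10, was higher by 14.6-fold (11.4 to 19.1), Msmo1, a later enzyme of the sterol pathway, by 13.3-fold (11.3 to 15.7), and Fdps, which makes farnesyl diphosphate, by 13.4-fold (9.15 to 20.4). Nsdhl, another sterol enzyme, was higher by 12.2-fold (9.59 to 15.6), and Insig1, whose product retains the sterol sensor complex in the endoplasmic reticulum, by 8.24-fold (7.51 to 9.06).

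Genes of fatty acid and triglyceride synthesis were also higher in the high-fat library, with 9 of 20 measured members at least 2-fold higher, 1 lower by as much and a median of 0.81, above all 10000 random lists. Thrsp, a lipogenic regulator, was higher by 20.7-fold (16.8 to 25.7), and Srebf1, which encodes the lipogenic transcription factor SREBP-1, by 11.6-fold (10.03 to 13.5). Fatty acid synthase, Fasn, measured 64.8 CPM in the chow library and 512 CPM in the high-fat library, a difference of 7.91-fold (7.32 to 8.57). The stearoyl-CoA desaturase gene Scd1 went from 1319.7 to 7048 CPM between the same libraries, or 5.34-fold (5.25 to 5.44). Mid1ip1, which encodes an activator of acetyl-CoA carboxylase, was higher by 7.39-fold (5.72 to 9.68). Outside the list, Aacs, which activates acetoacetate for lipid synthesis, was higher by 13.3-fold (10.1 to 17.9).

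Genes of fatty acid oxidation and targets of the nuclear receptor PPAR alpha lay the other way: 9 of 30 measured members were at least 2-fold lower in the high-fat library, 1 was higher by as much, and the median was -0.44, below all 10000 random lists. Cyp4a14, a fatty acid omega-hydroxylase, was lower by 8.96-fold (8.76 to 9.16), its relative Cyp4a10 by 6.82-fold (6.6000 to 7.05) and the acyl-CoA thioesterase gene Acot1 by 4.498-fold (3.93 to 5.17). Cpt1a, which encodes the enzyme that commits fatty acids to mitochondrial oxidation, was lower by 2.602-fold (2.51 to 2.69). Ppara itself measured 421 CPM in the chow library and 288 CPM in the high-fat library, and Fabp1, the liver fatty acid binding protein gene, was the member at least 2-fold higher, by 3.03-fold (2.96 to 3.11). The Cyp4a and Acot genes are close copies of one another, so reads may be divided among them. In the list of lipid droplets and fatty acid uptake, 2 of 16 measured members were at least 2-fold higher and 4 lower by as much, with a median of -0.21, at percentile 3.3 of the random lists. Fitm1, involved in droplet formation, was higher by 5.97-fold (4.61 to 7.84) and Pparg by 2.51-fold (1.81 to 3.53), while the droplet genes Plin4 and Cidec were lower by 3.63-fold (2.93 to 4.51) and 3.59-fold (2.73 to 4.77). The fatty acid transporter gene Cd36 measured 41.8 and 74.2 CPM in the chow and high-fat libraries.

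**Figure D1:**
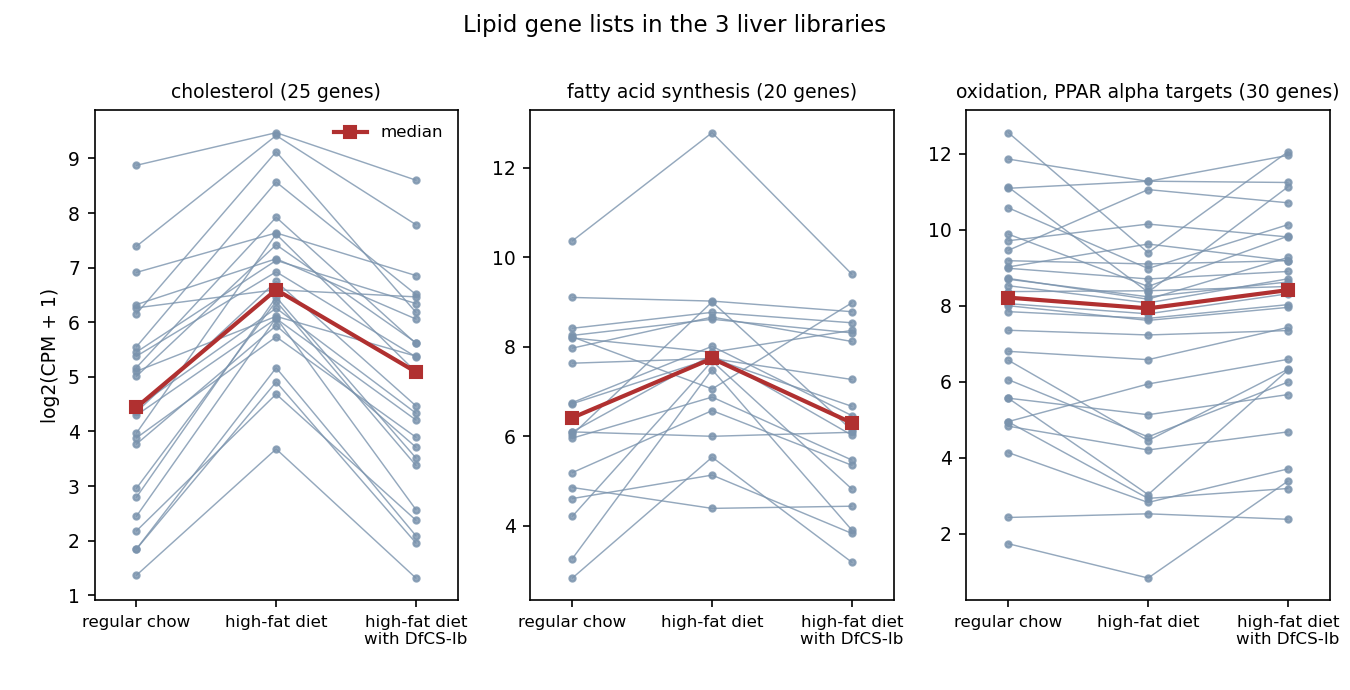
Each thin line joins the log2(CPM + 1) of 1 gene in the chow, high-fat and DfCS-Ib liver libraries (x axis), for the measured members of 3 lipid gene lists, and the thick line joins the members' medians. In the cholesterol panel all 25 genes were higher in the high-fat than in the chow library and lower in the DfCS-Ib than in the high-fat library, and the median log2 ratio of DfCS-Ib to chow was 0.12.

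Glucose metabolism genes differed in both directions, with 4 of 20 at least 2-fold higher and 6 lower by as much in the high-fat library (median -0.49, below all but 1 of the 10000 random lists). The higher members included the glycolytic gene Pklr, by 7.06-fold (6.31 to 7.93). Among the lower ones were Igfbp1, an insulin-repressed binding protein gene, by 4.58-fold (4.34 to 4.84), and Pck1, which catalyses a committed step of gluconeogenesis, by 2.23-fold (2.198 to 2.27). G6pc, the glucose-6-phosphatase gene, had a log2 ratio of -0.34. In the bile acid list, 4 of 19 members were at least 2-fold higher and 2 lower by as much (median 0.28, at percentile 98.7 of the random lists but inside the central 95% with RPKM, at 0.39). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was lower by 2.804-fold (2.53 to 3.12), and Cyp2c70, which makes muricholic acids, was higher by 3.8000-fold (3.57 to 4.05). For antioxidant and glutathione transferase genes, 5 of 20 were at least 2-fold higher and 0 lower by as much (median 0.42, above all but 3 of the 10000 random lists). Gstm3 was higher by 7.79-fold (5.65 to 10.97), Gsta3 by 3.63-fold (3.53 to 3.74) and Gclc, a subunit of the rate-limiting enzyme of glutathione synthesis, by 2.82-fold (2.69 to 2.96). Periportal hepatocyte markers were lower, with 6 of 13 at least 2-fold lower and 0 higher by as much (median -0.86, below all 10000 random lists). They included the urea cycle genes Asl and Ass1, lower by 4.03-fold (3.91 to 4.15) and 2.46-fold (2.38 to 2.54), and Etnppl, lower by 5.09-fold (4.85 to 5.34).

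Interferon response genes were higher in the high-fat library than in the chow library, 13 of 19 by at least 2-fold and 0 lower by as much, with a median of 1.19, above all 10000 random lists. Isg15, a ubiquitin-like protein gene, was higher by 5.96-fold (3.52 to 10.8), Oasl1 by 4.34-fold (3.21 to 5.99), Ifit3 by 4.82-fold (3.02 to 8.07) and Ifit1 by 4.16-fold (2.94 to 6.03). Genes with male-biased expression in mouse liver were higher, 8 of 16 by at least 2-fold and 0 lower by as much (median 0.67, above all 10000 random lists, and 0.29 with no filter on low values). Female-biased genes, several of them close copies, were lower, 5 of 9 by at least 2-fold and 1 higher by as much (median -1.53, below all 10000 random lists, but -0.19 with no filter on low values and -0.54 with RPKM). Hsd3b5, a male-biased steroid dehydrogenase gene on chromosome 3, 98618636 to 98645534, had the largest ratio above 1 among the named genes of this comparison: 32 counts in the chow library, 3620 in the high-fat library or 94.6-fold (66.9 to 138). On the female-biased side, the transcription factor gene Cux2 was lower by 13.2-fold (5.31 to 42.1), Cyp17a1, a steroid-synthesis cytochrome, by 7.83-fold (6.43 to 9.61) and Fmo2 by 5.61-fold (4.81 to 6.57).

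Among drug-metabolising cytochromes and their receptors, 5 of 20 were at least 2-fold higher and 1 was lower by as much (median 0.06, at percentile 73.4 of the random lists). Cyp2c55 was higher by 6.77-fold (4.33 to 11.1), Cyp2c29 by 5.32-fold (5.18 to 5.45) and Cyp2b10, a target of the receptor CAR, by 5.25-fold (4.11 to 6.78), while Por, the reductase that serves microsomal cytochromes, was lower by 4.25-fold (4.05 to 4.45).

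Outside the lists, Car3, a carbonic anhydrase abundant in liver (chromosome 3, 14863490 to 14872536), was higher in the high-fat library by 32.4-fold (30.5 to 34.5). Aqp8, a water channel, was higher by 20.04-fold (16.3 to 24.9) and Serpina7, the thyroxine-binding globulin gene, by 16.3-fold (10.9 to 25.5). The metallothionein genes Mt2 and Mt1, neighbours on chromosome 8 (Mt2 at chromosome 8, 94172618 to 94173567) whose products bind zinc and copper, were lower by 243-fold (149 to 426) and 78.6-fold (62.2 to 101), with 3252 and 16 counts of Mt2 in the chow and high-fat libraries. Slc16a5, of the monocarboxylate transporter family, was lower by 19.7-fold (14.8 to 26.9), the magnesium transporter gene Nipal1 by 18.03-fold (12.2 to 27.7), and Cyp26b1, a retinoic acid hydroxylase, by 16.6-fold (11.3 to 25.3). The stress-inducible gene Gadd45b was lower by 19.3-fold (9.87 to 42.98), the organic anion transporter gene Slco1a4 by 8.15-fold (7.58 to 8.78) and the leptin receptor gene Lepr by 8.25-fold (6.41 to 10.8). Fam107a had 1 count in the high-fat library, a ratio of 104-fold (18.2 to 4156) below chow. Gene models on the opposite strand overlap Bhlhe40, Car3, Cd5l, Col3a1, Cpt1a, Cux2, Cyp17a1, Dbp, Emr1, Etnppl, Fgf21, G0s2, Ifit1, Il1b, Npas2, Nxpe2, Plin4, Por, Serpina7, Slc13a2, Slc16a5, Socs2, Srebf1 and Usp2, and without a stated strand setting the reads of such pairs cannot be told apart. Ctcflos, a noncoding transcript that overlaps another gene model on its own strand, was lower by 12.7-fold (9.67 to 17.1).

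Acute phase genes showed no common direction between these libraries: 0 of 21 were at least 2-fold higher in the high-fat library and 4 lower by as much, and the median of -0.07 (at percentile 30.1 of the random lists) was above 0 without scaling factors (0.04), with the authors' RPKM (0.00) and with the 50 most abundant genes left out (0.05). Inflammatory genes had 1 of 15 members at least 2-fold higher and 0 lower by as much (median -0.15), clock genes 1 of 18 at least 2-fold higher and 3 lower by as much (median -0.04, but 0.06 without scaling factors), and respiratory chain genes a median of 0.07. The clock list joins genes of opposite phase, with 5 measured genes of the Arntl phase and 10 of the Dbp phase. Its median in any comparison therefore depends on how many of each it holds.

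Across 13153 measured genes, 457 were at least 2-fold higher in the high-fat library and 298 at least 2-fold lower, 60.5% of them higher. Without scaling factors the counts were 573 and 242 (70.3% higher), and with the authors' RPKM 447 and 207 (68.3%), so the balance of directions depended on the scaling here too. The SD of the log2 ratios over genes was 0.55, and counts drawn with no difference between the libraries gave 1 such gene.

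The comparison of the DfCS-Ib and high-fat libraries addressed the treatment on the same diet. Cholesterol genes were lower in the DfCS-Ib library, 20 of 25 by at least 2-fold and 0 higher by as much (median -2.06, below all 10000 random lists). Fatty acid synthesis genes were at least 2-fold lower in 11 of 20 cases and higher by as much in 1 (median -1.15, below all 10000 random lists). Fdps was lower by 10.7-fold (7.58 to 15.6), Mvd by 10.03-fold (6.95 to 14.98), Nsdhl by 8.77-fold (7.14 to 10.9), Sqle by 8.34-fold (6.86 to 10.2) and Hmgcs1, an early enzyme of the pathway, by 7.76-fold (7.21 to 8.37). Among the lipogenic genes, Thrsp was lower by 12.8-fold (10.8 to 15.2), Scd1 by 8.96-fold (8.76 to 9.16), Fasn by 7.39-fold (6.85 to 7.98), Srebf1 by 7.47-fold (6.62 to 8.46) and Aacs by 7.98-fold (6.399 to 10.1). The water channel gene Aqp8 was lower by 10.7-fold (9.15 to 12.5).

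Fatty acid oxidation and PPAR alpha target genes were higher in the DfCS-Ib library, 9 of 30 by at least 2-fold and 0 lower by as much (median 0.53, above all 10000 random lists). Cyp4a31 was higher by 10.9-fold (8.79 to 13.7), Cyp4a10 by 6.84-fold (6.62 to 7.07), Cyp4a14 by 6.31-fold (6.17 to 6.46) and Cpt1a by 2.51-fold (2.42 to 2.596). Ppara was higher by 2.15-fold (2.06 to 2.24), and Fgf21, a hepatokine gene of low abundance, had 10 and 101 counts in the high-fat and DfCS-Ib libraries, a ratio of 12.1-fold (6.32 to 26.03). In the lipid droplet list 5 of 16 members were at least 2-fold higher and 2 lower by as much (median 0.44, above all 10000 random lists). G0s2, an inhibitor of adipose triglyceride lipase, was higher by 8.53-fold (7.73 to 9.44), Pnpla2, which encodes that lipase, by 2.76-fold (2.499 to 3.05) and Plin5 by 2.89-fold (2.64 to 3.17), while Fitm1 was lower by 3.14-fold (2.57 to 3.86). Cidec was higher by 2.81-fold (2.11 to 3.77), Pparg lower by 2.23-fold (1.63 to 3.09), and Cd36 had a log2 ratio of -0.38. Glucose metabolism genes again differed both ways, 6 of 20 at least 2-fold higher and 3 lower by as much (median 0.28, at percentile 98.7 of the random lists but inside the central 95% with the 50 most abundant genes left out, at 0.13). Pklr was lower by 5.42-fold (4.897 to 6.004), whereas Igfbp1 was higher by 3.25-fold (3.07 to 3.44), Ppargc1a, a coactivator of gluconeogenic genes, by 2.75-fold (2.25 to 3.37) and Pck1 by 2.47-fold (2.44 to 2.51). The log2 ratio of G6pc was 0.03.

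Acute phase genes, whose secreted products the liver makes in inflammation, were higher in the DfCS-Ib library: 10 of 21 were at least 2-fold higher than in the high-fat library and 0 lower by as much, with a median of 0.94, above all 10000 random lists, and 1.52 with the 50 most abundant genes left out. The serum amyloid A genes Saa2 and Saa1, neighbours on chromosome 7 (Saa2 at chromosome 7, 46751777 to 46754314), were higher by 61.3-fold (48.5 to 78.6) and 33.000-fold (28.5 to 38.4). Orm2, an orosomucoid gene, was higher by 24.9-fold (16.9 to 38.1) and Lcn2, which encodes an iron-siderophore binding protein, by 6.86-fold (5.16 to 9.26). Mt2 and Mt1, which stand in the same list, were higher by 105-fold (64.2 to 184) and 34.7-fold (27.4 to 44.6), from 16 and 71 counts in the high-fat library, but remained below chow. Saa1 and Saa2 are near-identical copies, so the division of reads between them is uncertain. Inflammatory genes had 2 of 15 members at least 2-fold higher and 0 lower by as much (median 0.41, above all but 3 of the 10000 random lists, and 0.19 with no filter). Vcam1, an adhesion molecule gene, was higher by 4.402-fold (3.73 to 5.22) and Socs3, a feedback inhibitor of cytokine signalling, by 3.395-fold (2.47 to 4.74). The members were above the high-fat library in 11 of 15 cases; Il1b, the interleukin gene, was lower in the DfCS-Ib library by 2.66-fold (1.49 to 4.99), with 51 and 16 counts in the high-fat and DfCS-Ib libraries. Its log2 ratio on CPM plus 1 was -0.99, short of 2-fold. Beside these, all 14 macrophage and Kupffer cell markers had ratios above 1 in the DfCS-Ib library, 3 of them by at least 2-fold (median 0.69, above all 10000 random lists). Cd163, a haemoglobin scavenger receptor gene, was higher by 3.997-fold (3.49 to 4.58), Marco by 3.598-fold (2.405 to 5.51) and the pan-macrophage marker Emr1 by 2.08-fold (1.78 to 2.45). Monocyte markers had a median of 0.46 over 5 genes (at percentile 98.3 of the random lists), and 0.29, inside the central 95%, with RPKM. Erythroid markers were higher as well, with a median of 0.57 over 7 genes, 2 of them at least 2-fold higher.

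Outside the lists, Moxd1, a monooxygenase gene, was higher in the DfCS-Ib library by 30.4-fold (21.4 to 44.7), the ferritin receptor gene Scara5 by 13.1-fold (9.94 to 17.4) and the immediate early gene Egr1 by 12.5-fold (9.26 to 17.4). Cyp26b1 was higher by 11.6-fold (7.82 to 17.7). TrnG, a mitochondrial transfer RNA of 68 bases, was higher by 22.2-fold (14.8 to 34.6), with 30, 25 and 462 counts in the chow, high-fat and DfCS-Ib libraries.

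For circadian clock genes, 4 of 18 were at least 2-fold higher and 2 lower by as much (median 0.39, above all but 1 of the 10000 random lists): Usp2 was higher by 5.42-fold (3.92 to 7.64), Nr1d1 by 2.304-fold (2.07 to 2.56) and Dbp by 2.17-fold (1.63 to 2.897), whereas Npas2 was lower by 6.46-fold (3.53 to 12.9). Taken by phase, the medians were -0.77 for the Arntl phase and 0.84 for the Dbp phase. Antioxidant genes were lower, 5 of 20 by at least 2-fold and 0 higher by as much (median -0.39, below all 10000 random lists), led by Gstm3 at 8.15-fold (5.88 to 11.6) and Gclc at 3.26-fold (3.099 to 3.42). None of the 19 interferon response genes differed by 2-fold between the DfCS-Ib and high-fat libraries (median 0.09, at percentile 85.5 of the random lists). Male-biased and female-biased genes had medians of 0.09 and 0.17, inside the central 95% of random lists, and the first was -0.01 without scaling factors and with RPKM. Respiratory chain genes were lower by a small amount, 0 of 25 by 2-fold, with a median of -0.18, at percentile 0.79 of the random lists, which was -0.28 and inside the central 95% with RPKM.

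In all, 324 genes were at least 2-fold higher in the DfCS-Ib than in the high-fat library and 266 lower by as much, so that 54.9% were higher; counting noise alone gave 4 such genes, and the SD of the log2 ratios was 0.49. Without scaling factors the share was 43.4%, and with the authors' RPKM it was 44.7%, so the balance of directions depended on the scaling.

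**Figure D2:**
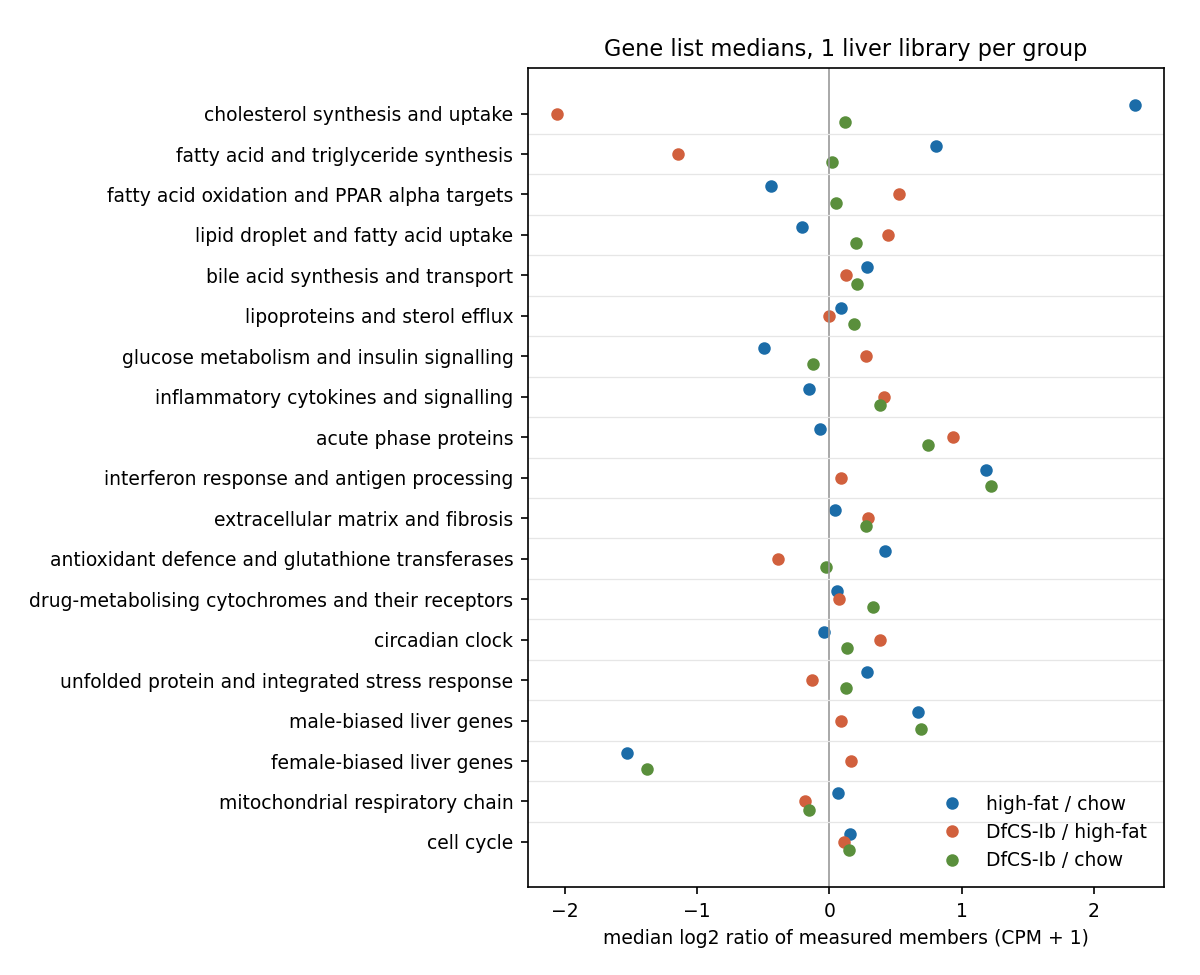
The x axis gives the median log2 ratio of the measured members of each of the 19 function lists (y axis), computed on CPM plus 1, for the high-fat over the chow library, the DfCS-Ib over the high-fat library and the DfCS-Ib over the chow library, with 1 library per group. Cholesterol genes had medians of 2.31, -2.06 and 0.12, and interferon genes 1.19, 0.09 and 1.23.

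The DfCS-Ib and chow libraries were compared to place the treated liver beside the normal one. Cholesterol genes had 1 of 25 members at least 2-fold higher, Msmo1 at 2.25-fold (1.86 to 2.74), and 0 lower by as much (median 0.12, at percentile 98.6 of the random lists but inside the central 95% with RPKM, at 0.10). Of 20 fatty acid synthesis genes, 0 were at least 2-fold higher and 0 lower by as much (median 0.02, at percentile 61.8 of the random lists). Of 30 fatty acid oxidation genes, 3 were at least 2-fold higher and 1 lower by as much (median 0.05, at percentile 71 of the random lists, but -0.03 with the 50 most abundant genes left out). Lipid droplet and fatty acid uptake genes were above chow in 11 of 16 cases, 1 of them by at least 2-fold (median 0.20, at percentile 99.6 of the random lists). Fasn measured 64.8 and 69.3 CPM in the chow and DfCS-Ib libraries, Srebf1 17.6 and 27.3, and Cpt1a 945 and 911. Scd1 had a log2 ratio of -0.74, Ppara 0.55, Cyp7a1 -0.48, Cd36 0.43, Cidec -0.33, Pparg 0.14 and G6pc -0.31. Vnn1, a pantetheinase gene of the PPAR alpha list, and G0s2 were higher in the DfCS-Ib library by 3.18-fold (2.81 to 3.62) and 4.505-fold (4.15 to 4.89).

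Other groups differed from chow in the DfCS-Ib library. All 19 interferon response genes were above chow, 14 of them by at least 2-fold (median 1.23, above all 10000 random lists), with Ifit1 at 5.07-fold (3.58 to 7.34) and Usp18, which removes Isg15 from proteins, at 5.22-fold (3.49 to 8.06). Acute phase genes were above chow in 17 of 21 cases, 7 were at least 2-fold higher, and 2, Mt1 and Mt2, were lower by as much (median 0.75, above all 10000 random lists, and 0.39 with a mean of at least 5 CPM). Saa2 was higher by 69.96-fold (53.2 to 93.9), Saa1 by 41.7-fold (34.9 to 50.3), Saa3 by 11.4-fold (6.16 to 23.4), Orm2 by 9.21-fold (7.06 to 12.2) and Lcn2 by 6.81-fold (5.02 to 9.43). Macrophage and Kupffer cell markers were above chow in all 14 cases, 6 by at least 2-fold (median 0.96, above all 10000 random lists), with the Kupffer cell lectin gene Clec4f at 2.39-fold (2.22 to 2.58) and Cd5l at 2.22-fold (2.05 to 2.41). In the inflammatory list 2 of 15 were at least 2-fold higher and 0 lower by as much (median 0.38, above all but 1 of the 10000 random lists). Male-biased genes were above chow in 15 of 16 cases, 5 of them by at least 2-fold, and 0 were lower by as much (median 0.69, above all 10000 random lists), with Hsd3b5 at 18.8-fold (13.2 to 27.8). All 9 female-biased genes were below chow, 6 of them by at least 2-fold (median -1.38, below all 10000 random lists, but -0.37 with no filter and -0.74 with RPKM). The drug-metabolising list had 4 of 20 members at least 2-fold higher and 1 lower by as much (median 0.33, above all but 4 of the 10000 random lists), led by Cyp2c29 at 3.81-fold (3.71 to 3.905) and Cyp2b10 at 4.09-fold (3.17 to 5.33), both of which were also above chow in the high-fat library. Clock genes were above chow in 10 of 18 cases and below it in the others; 4 were at least 2-fold higher and 0 lower by as much (median 0.14, at percentile 97.7 of the random lists, but inside the central 95% with RPKM, at 0.07), with Dbp at 3.93-fold (2.71 to 5.83), Nr1d1 at 3.08-fold (2.72 to 3.49) and Bhlhe40 at 2.05-fold (1.79 to 2.35). Periportal markers had a median of -0.59, below all 10000 random lists, with Etnppl lower by 3.95-fold (3.77 to 4.14).

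Of the genes chosen by size alone, Moxd1 (chromosome 10, 24223517 to 24302783) was higher than chow by 58.1-fold (34.4 to 107), Scara5 by 8.52-fold (6.68 to 11.01), Nxpe2 by 6.34-fold (4.65 to 8.82) and TrnG by 15.4-fold (10.7 to 23.2). The major urinary protein genes Mup17 and Mup11 were higher by 27.6-fold (15.2 to 55.9) and 7.798-fold (6.79 to 8.996), in a family of near-identical copies among which reads cannot be placed with certainty. Cyp26a1, a retinoic acid hydroxylase, was lower by 6.26-fold (4.39 to 9.16), Cux2 by 9.14-fold (3.94 to 25.98), Cyp3a16, one of a family of close copies, by 4.096-fold (2.84 to 6.04) and Acot3 by 3.67-fold (2.88 to 4.703). The transcriptional repressor gene Bcl6 was lower by 3.51-fold (2.83 to 4.396), Lrrc15 by 5.68-fold (2.88 to 12.5), the cytokine signalling inhibitor gene Socs2 by 3.31-fold (2.67 to 4.14) and the citrate transporter gene Slc13a2 by 4.3000-fold (2.47 to 7.94). Sdsl, Sik1, a kinase gene, and Fmo2 were lower by 2.82-fold (2.42 to 3.302), 2.71-fold (2.36 to 3.13) and 2.65-fold (2.34 to 3.001). The DfCS-Ib library had 213 genes at least 2-fold above chow and 57 below, 78.9% of them higher, where counting noise alone gave 3, and the SD of the log2 ratios was 0.37. That share was 68.9% with the 50 most abundant genes left out, when 116 genes were lower.

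Genes that set the high-fat library apart from the other two were the largest such group. A gene was counted where 1 library lay at least 2-fold from both others while these lay within 1.5-fold of each other, and this held for 288 genes of the high-fat library (151 higher, 137 lower), 85 of the chow library (17 higher, 68 lower) and 40 of the DfCS-Ib library (36 higher, 4 lower). With counting noise alone the numbers were 1, 0 and 0. Without scaling factors 63.3% of the high-fat genes were higher in that library, against 52.4%, and 64.1% with RPKM. It was 46.6% with a pseudocount of 0.1 and 48.8% with a mean of at least 5 CPM. For the DfCS-Ib library the share was 90.0%, against 62.7% with RPKM and 66.7% with the 50 most abundant genes left out. Among the 457 genes higher in the high-fat than in the chow library, 193 (42.2%) were at least 2-fold lower in the DfCS-Ib library than in the high-fat one, 260 lay within 1.5-fold of chow in the DfCS-Ib library, and 90 were still at least 2-fold above chow. Of the 298 lower genes, 181 (60.7%) were at least 2-fold higher in the DfCS-Ib library, 193 lay within 1.5-fold of chow and 31 were still at least 2-fold below. Counting noise alone put 1 gene 2-fold apart in the first comparison and 4 in the second. Independent lists of the same sizes would share 9.24 and 7.34 genes with the treatment comparison. Both comparisons contain the high-fat library, so part or all of the excess may come from that library alone, and neither value allows for the spread between mice.

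Medians for the high-fat over chow, DfCS-Ib over high-fat and DfCS-Ib over chow libraries were 0.09, 0.00 and 0.19 for lipoproteins and sterol efflux. The second of these was -0.10 without scaling factors and with RPKM. The third stood apart (at percentile 99.5 of the random lists) but lay inside the central 95% with RPKM, at 0.13, and with the 50 most abundant genes left out, at 0.09. They were 0.04, 0.30 and 0.28 for extracellular matrix genes. The last 2 stood apart, each at percentile 99.8, although the value against the high-fat library was 0.14 and inside the central 95% with no filter. Col3a1, a fibrillar collagen gene, was higher in the high-fat than in the chow library by 2.34-fold (1.87 to 2.94). For unfolded protein and stress genes they were 0.28, -0.13 and 0.13, the first of which stood apart (at percentile 98.8 of the random lists), with 1 of 20 members at least 2-fold higher, 1 lower by as much and 13 above 0. The lower member was Asns, the asparagine synthetase gene, by 4.64-fold (3.14 to 7.02) in the high-fat library. Cell cycle genes had 0.15, 0.11 and 0.15, where the second was -0.16 with RPKM. The drug-metabolising list had 0.07 for the DfCS-Ib over the high-fat library, and -0.03 without scaling factors. Bile acid genes had 0.13 for the same libraries and 0.21 for the DfCS-Ib over the chow library (at percentile 99.5 of the random lists), where 3 of 19 were at least 2-fold higher and 0 lower by as much. For the DfCS-Ib over the chow library, the median of glucose metabolism genes was -0.12, at percentile 1.94 of the random lists, but inside the central 95% with DESeq2 size factors. The medians were -0.02 for antioxidant genes and -0.16 for the respiratory chain (at percentile 0.32 of the random lists). Por was higher in the DfCS-Ib than in the high-fat library by 5.096-fold (4.87 to 5.34).

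Cell type and zone markers gave the following medians in the same order of comparisons. Hepatocyte markers (14 genes) had -0.21, 0.12 and -0.01, sinusoidal and vascular endothelium (11) -0.04, 0.16 and 0.12, and stellate cells and fibroblasts (10) -0.17, 0.27 and 0.04. The stellate value for the DfCS-Ib over the high-fat library stood apart (at percentile 98.3 of the random lists) but was 0.14 and inside the central 95% with RPKM. The endothelial value for the high-fat over the chow library was 0.06 without scaling factors and 0.05 with RPKM. Cholangiocyte markers (6) had 0.11, -0.31 and 0.00, the second being -0.19 with RPKM and the last -0.06 with the 50 most abundant genes left out. Erythroid markers (7) had -0.16, 0.57 and 0.43, and the last 2 stood apart, at percentiles 99.9 and 99.8, with 6 and 7 of 7 genes above 0. Macrophage and Kupffer cell markers had 0.23 for the high-fat over the chow library, and monocyte markers -0.04 and 0.64 for the comparisons with chow. The first monocyte value was 0.05 without scaling factors, 0.12 with the 50 most abundant genes left out and 0.42 with RPKM, and the second stood apart (at percentile 99.7 of the random lists). Pericentral markers (13) had 0.28, 0.05 and 0.33. The second of these was -0.05 without scaling factors and with RPKM and -0.11 with the 50 most abundant genes left out. The third stood apart (at percentile 99.8 of the random lists) but lay inside the central 95% with the 50 most abundant genes left out, at 0.16. Periportal markers had 0.36 for the DfCS-Ib over the high-fat library (at percentile 98.3 of the random lists), inside the central 95% with the 50 most abundant genes left out, at 0.23. Adipocyte markers (3) had -0.16, 0.45 and 0.23, the second being -0.11 with no filter. B and plasma cell markers (2) had -0.13, 0.63 and 0.50, and neutrophil markers (2) 0.20, 0.28 and 0.48. A single T and NK cell marker reached the expression minimum (0.44, -0.26, 0.18), as did a single exocrine pancreas marker (1.71, -1.17, 0.54), and 0 of the skeletal muscle markers did.

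**Figure D3:**
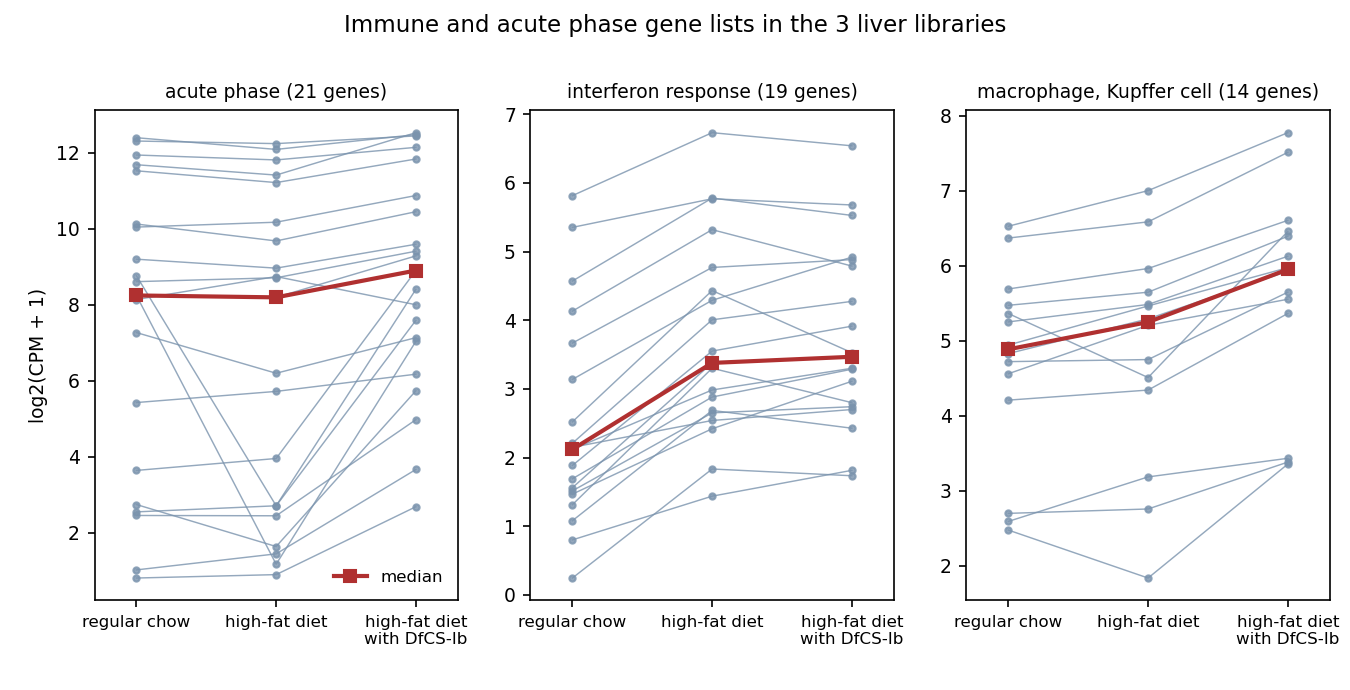
Thin lines join the log2(CPM + 1) of each measured gene of the acute phase, interferon response and macrophage and Kupffer cell lists across the chow, high-fat and DfCS-Ib liver libraries (x axis), and the thick line joins the medians. Interferon genes were lower in the chow library than in the other two, while the macrophage markers were highest in the DfCS-Ib library, with median log2 ratios of 0.69 to the high-fat and 0.96 to the chow library.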

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

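The versions without TMM factors, with DESeq2 size factors, with RPKM, with thinned libraries and with a counting interval were chosen only after the result was seen. Of 861 list medians recomputed, 22 crossed the bounds of the central 95% of random lists and 839 stayed on their side. Of 5283 values for named genes, 90 crossed 2-fold and 5193 did not, and of 117 counts 30 moved by over 1.5 times and 87 did not. None of the medians outside those bounds and none of the genes at least 2-fold apart changed sign. With a pseudocount of 0.1, the genes higher and lower were 704 and 464 for the high-fat over the chow library, 507 and 407 for DfCS-Ib over the high-fat library and 413 and 170 for DfCS-Ib over chow, and 174 and 95 genes set the chow and DfCS-Ib libraries apart. With a mean of at least 5 CPM, DfCS-Ib over chow gave 140 higher and 30 lower, and 22 genes set DfCS-Ib apart; with the 50 most abundant genes left out, 116 were lower than chow. At 1.5-fold the counts were 1370 and 1015, 1002 and 942, and 748 and 402 in the same order, with 399, 1009 and 259 genes for the chow, high-fat and DfCS-Ib libraries apart. At 4-fold they were 67 and 62, 47 and 45, and 20 and 3, with 3, 37 and 8 genes apart. The thresholds and the filter change the number of genes that can pass by construction; for the others the cause was not tested. Without TMM factors the median of all genes shifted by 0.10 for the high-fat over the chow library and by -0.09 for DfCS-Ib over the high-fat library. TMM scaling was itself listed as an alternative and is the scaling used throughout, and non-overlapping intervals from the files could not be run because the files give none; the counting interval removed no gene from any count. Depth limits genes with few reads, such as Fam107a, whose ratio of 104-fold below chow has a counting interval of 18.2 to 4156, and with 1 library per group no version tests the spread between mice.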

Other observations

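The tests of meal timing, exchanged labels, leukocytes and shared Saa reads, and the gene families here, were chosen only after the result was seen. Carboxylesterases, which hydrolyse lipid esters and drugs, were higher in the high-fat than in the chow library: 7 of 13 measured members by at least 2-fold, with a median log2 ratio of 1.09, and 0 lower by as much. They were lower in the DfCS-Ib than in the high-fat library (median -0.46, 11 of 13 below 0) and above chow there (median 0.56), in a family of close copies. With no filter on low values the medians of 18 members were 0.66, -0.17 and 0.24. Interferon-inducible GTPases of the Gbp and Irg families had 5 of 13 members at least 2-fold higher in the high-fat than in the chow library and 6 in the DfCS-Ib library, with medians of 0.84 and 0.97, and a median of 0.17 between the DfCS-Ib and high-fat libraries. With no filter the medians over 18 members were 0.42 and 0.74 above chow and 0.11 between those libraries. With RPKM they were 0.63, 0.62 and 0.06 over 6 members, and with a pseudocount of 0.1 they were 1.22, 1.44 and 0.19. Without TMM factors the last was 0.08. Major urinary protein genes, secreted pheromone carriers with male-biased expression, had medians of 1.31, 0.74 and 2.46 over 4 measured genes for the high-fat over chow, DfCS-Ib over high-fat and DfCS-Ib over chow libraries, and 0.21, 0.43 and 0.49 over 11 with no filter.

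Mitochondrial ribosomal proteins differed by small amounts in many members. Of 69, 53 were higher in the high-fat than in the chow library (median 0.22) and 58 lower in the DfCS-Ib than in the high-fat library (median -0.24), with 0 at 2-fold in either. Complement components had medians of 0.40, 0.24 and 0.39 over 17 genes in the order above, and UDP glucuronosyltransferases 0.15, -0.23 and -0.13 over 18. With no filter they were 0.21, 0.05 and 0.33 over 27 complement genes and 0.15, -0.11 and 0.00 over 21 glucuronosyltransferases. Without TMM factors the high-fat over chow value of the glucuronosyltransferases was 0.26, and the DfCS-Ib over high-fat value of the complement genes was 0.145, or 0.15 with the 50 most abundant genes left out. Serpins had 3 of 28 members at least 2-fold higher in the high-fat than in the chow library (median 0.23) and 4 in the DfCS-Ib than in the chow library (median 0.37), with medians of 0.08 and 0.25 over 42 with no filter. The first of these was 0.36 with a mean of at least 5 CPM and with the 50 most abundant genes left out.

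Sterol and fatty acid synthesis genes were high, and PPAR alpha target genes low, in the high-fat library alone. A difference in the time since the last meal is a candidate explanation: 20 fasting-induced genes outside the lipid lists, some of them shared with the glucose list, had a median log2 ratio of -0.724 for the high-fat over the chow library (-1.04 to -0.30 over 10000 resamples of the genes), below all 10000 random lists, and 0.891 for DfCS-Ib over the high-fat library, above all of them. Both medians contain the high-fat library, so the second is not separate support. Shared members such as Igfbp1 (log2 ratio of -2.19 for the high-fat over the chow library) had been seen to be low before the list was chosen. A difference in time of day stays open, since clock genes of opposite phase differed by 0.361 between the high-fat and chow libraries (-0.56 to 1.76) and by -1.60 between the DfCS-Ib and high-fat libraries, while the DfCS-Ib library also differed from chow, with medians of -0.57 for the Arntl phase and 0.42 for the Dbp phase. Exchanged chow and high-fat labels stay open too: 11 genes raised by long high-fat feeding had a median of 0.461 (-1.67 to 0.989), in the direction of the labels and at percentile 99.8 of the random lists with 8 of 11 above 0, but with Cidec, Plin4 and Apoa4 lower and Pparg and Cd36 higher in the library labelled high-fat. The diet and DfCS-Ib themselves cannot be separated from these explanations with 1 library per group, and remain as untested biological ones.

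Acute phase genes were high in the DfCS-Ib library alone. More leukocytes in that piece of liver would, as the source of the largest differences, raise their markers several-fold. Instead 24 leukocyte markers had a median of 0.631 over the high-fat library (0.43 to 0.773 over 10000 resamples of the genes), with 23 of the 24 above 0, and 0.898 over chow. Such resamples treat the genes as independent and do not cover the spread between mice or pieces of liver. Of these markers, 14 belonged to the macrophage and Kupffer cell list, whose median of 0.69 was known before the test was chosen. Their values argue against macrophages as the source of the largest differences, such as those of Saa1 and Saa2. Only 2 neutrophil markers and 1 T and NK cell marker were measured, so the median cannot decide on rarer leukocytes. The acute phase list's own medians were 0.94 over the high-fat library and 0.75 over chow, so a part in the smaller differences stays open. Reads shared between Saa1 and Saa2 could not raise the 7 list members outside the Saa genes that were at least 2-fold higher than in the high-fat library. Of these 7, 5 were outside the metallothioneins Mt1 and Mt2, which lay below chow, and the Orm genes are themselves close copies. The members had been counted before this question was put, and they leave the division of reads between Saa1 and Saa2 undecided. An acute phase response in the mice of this library, from the treatment, the gavage or an infection, may remain, and none of these was tested.

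Male-biased genes and interferon genes were low in the chow library alone. A female animal among the chow mice is argued against by 4 Y-linked genes and by Xist, with at most 2 counts in a library. The Y-linked genes had a median log2 ratio of 0.319 for chow over the mean of the other libraries, with 0.132 the lowest and 0.389 the highest of the 4. Fewer leukocytes in the chow piece of liver may account for part of the interferon difference and stay open. Leukocyte markers had a median of -0.593 for chow over the mean of the other libraries (-0.731 to -0.405 over 10000 resamples of the genes). That mean joins unlike libraries: the leukocyte median was 0.898 for DfCS-Ib over chow and 0.631 for DfCS-Ib over high-fat. Macrophage markers had 0.23 for high-fat over chow (at percentile 97.3 of the random lists), where interferon genes had 1.19. Interferon genes had 1.23 for DfCS-Ib over chow and 0.09 for DfCS-Ib over high-fat, so they did not follow the leukocyte markers. The diet, shared by the other libraries, is an untested biological explanation. With 1 library per group it cannot be told apart from other traits of the mice in the chow library.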
